A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

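RNA was measured by sequencing in 9 libraries of ligamentum flavum, the elastic ligament between the laminae of neighbouring vertebrae, from male New Zealand white rabbits aged 70 weeks. Per the labels' protocols, rabbits aged 18 weeks had the supraspinal muscle at L3-4 resected and the levels on either side fused with instrumentation. The labels give 3 groups of 3 libraries: sham operation (Control), the fused level (Fused) and the level of intervertebral stress concentration (ISC). Per the labels' protocols, libraries were made from total RNA with a kit that keeps the strand. Replicate numbers come from the sample titles. The labels do not say which libraries share an animal, or that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples.

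Reads were aligned to the rabbit genome oryCun2 (Broad) with TopHat, named in the submitters' processing notes, and analysed with Cufflinks, per the series' design text; versions are not given in the sources used here. The authors deposited 3 tables, one per pair of groups, each with the same scaled values of all 9 libraries for 23407 named gene rows; the largest difference was 0. The deposited values are a normalized signal per gene that the authors made by dividing read counts by a size factor of the library (TMM, as the deposited tables are named). The counting tool, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be assigned to either gene. In every library 100% of the values were whole multiples of the library's smallest value within a tolerance of 1e-06, so reads could be recovered by division. In Fused replicate 2 and ISC replicate 3 the value of 1 read lies so near 1 (1.0058 and 1.0032) that such multiples are hard to tell from rounding. The authors' deposited tables also hold their log2 fold change, with text in place of a number where a group was at 0, p-values and q-values, a rank score and a call. The calls correspond to a q-value under 0.1. A row without a gene name (1 row) holds only the authors' group averages and was left out. Of 8020 rows with a locus identifier for a name, 764 received a symbol through a RefSeq gene table of another rabbit assembly (mOryCun1.1), used for names only. Coordinates are those of the deposited tables, on oryCun2.

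Recovered reads per library ranged from 1233155 to 1869209, so that 3 reads corresponded to a scaled value between 2.40 and 3.58. Values below that are limited by counting error. The test was chosen by rules written before the data were examined, which named limma for normalized values. For each pair of groups, limma 3.58.1 (R 4.3.3) was fitted to log2(value + 1) with a mean-variance trend, for genes with a value of 1 or more in at least 3 of the 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. For each of 35 gene lists fixed before the data were examined, camera tested whether the tested members shifted relative to the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison. Calls of members are given over all genes and adjusted over the list alone. The genes named in the text follow a rule fixed beforehand: up to 8 called genes with the largest rise and the largest fall whose groups do not overlap, filled to 5 by the smallest p and then given as values; a panel of 12 matrix, growth factor and cytokine genes; and 3 members of each list past the test. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

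The fit and the list test were tested on simulated counts with 2-fold, 4-fold and 8-fold changes in a random set of genes, drawn from the real means, depths and dispersions. For ISC against Control, 1.79% of the tested 2-fold changes, 44.3% of the 4-fold and 67.2% of the 8-fold changes were recovered, with 1 false call among 14530 genes. For Fused against Control the shares were 9.23%, 58.8% and 82.1%, with 6 false calls among 14970 genes. For ISC against Fused they were 1.32%, 22.2% and 63.6%, with 9 false calls among 15479 genes. With no changed gene, each comparison gave 0 calls. With the heat shock list shifted 2-fold, its camera adjusted p was 3.28e-08, 2.64e-08 and 6.04e-06 in the same order of comparisons. Other lists called then numbered 1, 0 and 0. Each gene was drawn independently and each setting was drawn once, so the simulation lacks the variation that real libraries share across genes. It cannot show how the fit or the list test behaves under such variation.

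Alternatives chosen before the data were examined were median centring, quantile normalization, no filter and a minimum value of 10, pseudocounts of 0.1 and 5, limma without the trend and with array weights, all 9 libraries in a single fit, the replicate number as a block, a threshold of 0.1, removal of the skeletal muscle list before scaling, and each library left out. The list test was repeated with an estimated correlation and with fry. Chosen after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, edgeR without Fused replicate 2 and ISC replicate 3, removal of the libraries richest in haemoglobin reads, the mean of the erythroid list as a covariate, and separate Control libraries for the correlation of changes. No deposited column of per-sample values was left unused.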

Results

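Gene expression was measured by RNA sequencing in the ligamentum flavum of 70-week-old male rabbits, in 3 libraries from sham-operated animals (Control), 3 from a fused spinal level (Fused) and 3 from the level where stress concentrates between fused levels (ISC). By its title, the series asks how long-term mechanical stress changes gene expression in this ligament. Between 1233155 and 1869209 reads per library lay in genes, and between 14700 and 15954 genes had a value above 0. Libraries of the same group correlated with r between 0.824 and 0.965 across genes, and no library pair of a group agreed within counting noise (chi-square per gene of at least 6.07).

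The libraries differed in reads from blood cells. Haemoglobin genes took 0.248%, 0.0963% and 0.233% of the reads in Control replicates 1 to 3. They took 1.55%, 5.64% and 6.41% in Fused replicates 1 to 3 and 0.480%, 5.00% and 0.421% in ISC replicates 1 to 3. The first principal component, with 47.5% of the variance, placed Fused replicates 2 and 3 and ISC replicate 2 (scores 83.1, 65.0 and 66.8) apart from the other 6 libraries, whose scores lay between -58.1 and 1.24. Mitochondrial genes took between 4.29% and 14.5% of the reads.

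**Figure D1:**
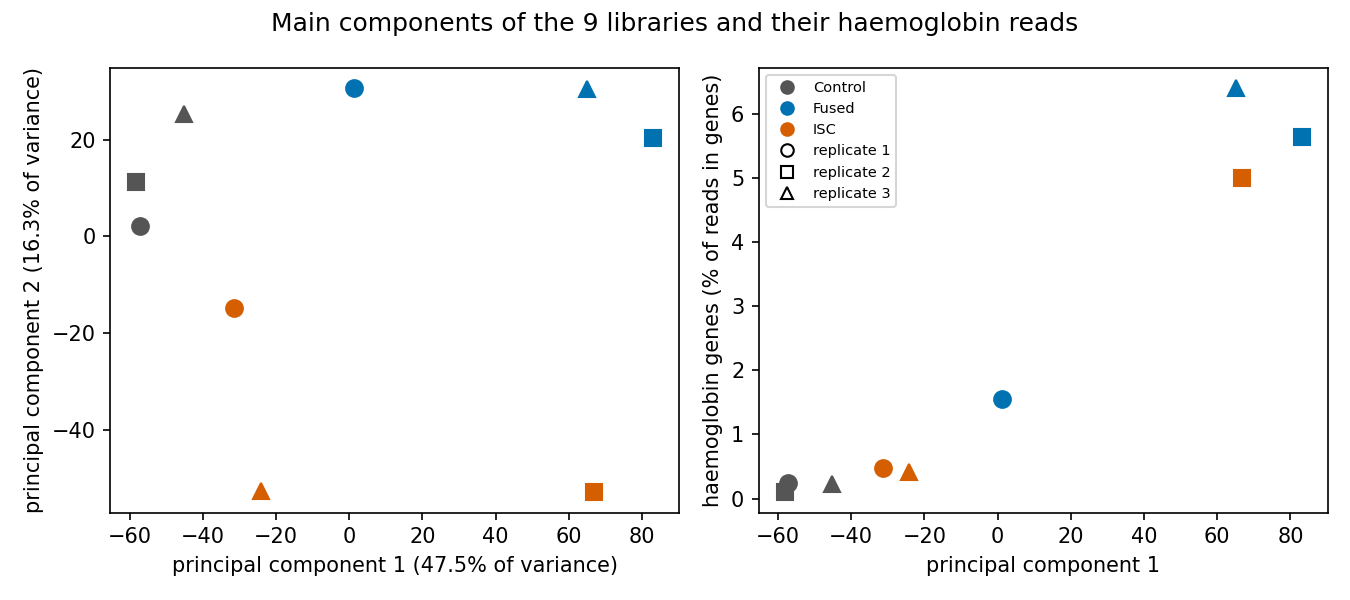
Left, principal components 1 and 2 of log2(value + 1) of the 9 libraries; right, principal component 1 against the percent of reads in haemoglobin genes. Colours are groups and shapes replicates; Fused replicates 2 and 3 and ISC replicate 2, with 5.64%, 6.41% and 5.00% haemoglobin reads, lie at the right.

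ISC was compared with Control to ask what changed at the level under concentrated stress. Some collagens of cartilage rose in the ISC libraries. COL2A1, the main collagen of cartilage (scaffold Un0251, 72092 to 94424), had a scaled read count of 5488 ± 2110 (SD, n = 3) in ISC against 10.5 ± 7.88 in Control, a log2 change of 9.09 (SE 0.538, adjusted p = 0.00282). COL9A1 (chromosome 12, 56889129 to 56995695) rose from 0.604 ± 0.525 to 82.3 ± 4.91, COL9A2 (chromosome 13, 126185170 to 126198369) from 5.66 ± 3.32 to 167 ± 15.1 and COL11A1 (chromosome 13, 61054050 to 61262804) from 62.5 ± 65.1 to 2403 ± 545, with adjusted p of 0.00465, 0.00465 and 0.0326 in limma. These collagens assemble with type II collagen into cartilage fibrils. SRPX2 (chromosome X, 88706898 to 88732246) rose from 7.64 ± 3.23 to 79.7 ± 12.1 (adjusted p = 0.0261), and RAB9A, a small GTPase of endosomes (scaffold Un1080, 17350 to 17919), had 0 reads in each Control library and 60.7 ± 28 in ISC (adjusted p = 0.00465). In all, 6 genes rose and 1 fell among 14348 tested; the gene that fell, LOC100358370, was at 0.334 ± 0.579 against 65.7 ± 32.2. It has no symbol and was named after its values were seen. The groups did not overlap in 18.3% of the tested genes, where chance gives 10%.

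Of 17 tested members of the cartilage list, 4 rose over all genes and 12 when adjusted over the list alone; 15 had a positive change and the median log2 change was 2.93 (camera adjusted p = 1.56e-14; adjusted p = 0.333 with an estimated correlation). ACAN, the large proteoglycan of cartilage, was at 2568 ± 1110 in ISC and 559 ± 351 in Control, and SOX9, the transcription factor of chondrocytes, at 122 ± 36.1 and 76.6 ± 47.4; neither passed the test (adjusted p = 0.314 and 0.519). The cartilage list was the only list past the fry test in this comparison (adjusted p = 0.0136).

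Adipocyte genes fell as a list: all 11 tested members were lower, none over all genes and 11 when adjusted over the list alone, with a median of -2.62 (camera adjusted p = 2.57e-11; adjusted p = 0.667 with an estimated correlation). THRSP was at 5.15 ± 1.74 in ISC and 129 ± 91.1 in Control, LEP, the gene of leptin, at 1.78 ± 0.514 and 38.1 ± 24.7, and CIDEC, a lipid droplet protein, at 8.88 ± 3.75 and 132 ± 87.9. No falling gene with a symbol passed the test; genes with values next in line included AKAP12 (153 ± 7.88 against 369 ± 45.2), PCK1, GPD1 and KLB, with limma adjusted p between 0.0662 and 0.129. The skeletal muscle list also shifted down (median -1.60, adjusted p = 0.0181; adjusted p = 0.671 with an estimated correlation), with 0 of 17 members called. The mean log2 value of this list was 7.34, 1.13 and 4.27 in Control replicates 1 to 3 and 4.83, 1.35 and 1.47 in ISC replicates 1 to 3. The call was lost, with a median of -0.10 without Control replicate 1 (adjusted p = 0.808), -0.85 without ISC replicate 2 (0.228) and -1.11 without ISC replicate 3 (0.223). It was kept, with a median of -2.90, without Control replicate 2 and, with -2.61, without ISC replicate 1.

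Matrix and fibroblast lists shifted up with no member called over all genes. Medians were 0.77 for fibrillar collagens (adjusted p = 0.000947), 0.64 for other collagens (0.016), 1.001 for small proteoglycans (0.00537), 0.86 for activated fibroblast genes (0.0156) and 0.75 for glycolysis and hypoxia genes (0.000773). Adjusted over the list alone, 1, 0, 1, 0 and 3 of their members rose. The fibrillar collagen median was 0.44 without ISC replicate 2 and 0.48 without Control replicate 3, with the call kept. PLOD2, a collagen lysyl hydroxylase, was at 845 ± 492 in ISC and 218 ± 47.8 in Control, FMOD, fibromodulin, at 5492 ± 2800 and 1262 ± 503, and FN1, fibronectin, at 24190 ± 6980 and 8548 ± 1970. Blood and proliferation lists shifted up as well, with haemoglobin reads highest in ISC replicate 2: cell cycle (median 2.18, adjusted p = 1.64e-06), erythroid (3.20, 0.000262), macrophage (1.19, 0.000913), granulocyte and mast cell (3.52, 0.00327) and lymphocyte (0.77, 0.0144). Adjusted over the list alone, 0, 7, 3, 4 and 0 of their members rose. Without ISC replicate 2 the medians of the cell cycle, erythroid and granulocyte and mast cell lists were 0.86, 1.77 and 2.06, with the calls kept. TOP2A, a topoisomerase of dividing cells, was at 103 ± 148 in ISC and 5.80 ± 1.09 in Control. With an estimated correlation the adjusted p of these 10 lists was 0.667 or 0.671. Elastin (ELN) was at 2257 ± 1320 and 1480 ± 528 (adjusted p = 0.678), and the elastic fibre list did not shift (median 0.11, adjusted p = 0.878). IL6 was read in Control replicate 1 and ISC replicate 3 and in no other library, and was not tested.

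The count of 7 genes became 22 without Control replicate 1, 38 without ISC replicate 1, and 4 without Control replicate 2, Control replicate 3 or ISC replicate 3. It was 3 with the replicate block, 14 in a fit of all 9 libraries, 4 with a pseudocount of 0.1, 5 with edgeR and 228 with DESeq2, and without ISC replicate 1 the count of 13 lists became 21. With limma COL2A1, COL9A1 and RAB9A kept their calls without each library, while edgeR called 0 genes without Control replicate 3 (743 at an unadjusted p under 0.05; limma 4). COL9A2 lost its call without ISC replicate 3 (adjusted p = 0.052), and COL11A1 and SRPX2 lost theirs without Control replicate 2, Control replicate 3, ISC replicate 2 or ISC replicate 3 (adjusted p between 0.119 and 0.232). The fall of LOC100358370 lost its call without Control replicate 2 or Control replicate 3, with the replicate block and with a pseudocount of 0.1, where 0 genes fell. Without ISC replicate 2 list calls were lost for glycolysis and hypoxia (median 0.36, adjusted p = 0.129), other collagen (0.34, 0.0812) and lymphocyte genes (0.80, 0.183). Without ISC replicate 3 they were lost for macrophage (1.02, 0.129), activated fibroblast (0.54, 0.0832) and other collagen genes (0.44, 0.0817), and without Control replicate 1 for activated fibroblast (0.80, 0.0561) and other collagen genes (0.64, 0.0591).

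Fused was compared with Control to ask what changed at the fused level. Some genes of blood and marrow cells rose in the Fused libraries and some genes of the ligament matrix fell. HEMGN, a protein of blood cell precursors (chromosome 1, 15127522 to 15146950), had a scaled read count of 444 ± 304 (SD, n = 3) in Fused against 4.13 ± 1.64 in Control, a log2 change of 6.09 (SE 0.65, adjusted p = 0.0142). The neutrophil genes CAMP, LCN2, S100A8 and MMP8 rose by 5.90, 5.81, 5.75 and 5.72 on the log2 scale. MCP-1, as the table names it (scaffold Un0015, 172905 to 174436), rose by 6.02 and DMP1, a matrix protein of osteocytes, by 5.95. MCP-1 is here a gene row apart from the chemokine gene CCL2, which is named outside the rule. CCL2 was at 5.81, 5.03 and 1.09 in Fused replicates 1 to 3 and at 17.9, 3.19 and 6.09 in Control replicates 1 to 3. In all, 584 genes rose and 382 fell among 14686 tested. The groups of each called gene did not overlap; they did not overlap in 29.3% of the tested genes, where chance gives 10%.

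The lists of blood cells and dividing cells rose beside haemoglobin reads of 1.55% to 6.41% in Fused and at most 0.248% in Control. Of 7 tested erythroid genes 7 rose (median 4.90, adjusted p = 2.61e-07); SLC4A1, the anion exchanger of red cells, went from 19.7 ± 10.4 to 1348 ± 949. Of 9 granulocyte and mast cell genes 7 rose, and 8 when adjusted over the list alone (median 5.499, adjusted p = 8.99e-07); S100A9 went from 39.0 ± 17.2 to 2549 ± 1950. Of 21 cell cycle genes 15 rose, and 21 when adjusted over the list alone (median 3.61, adjusted p = 1.65e-12); TOP2A went from 5.80 ± 1.09 to 150 ± 101. Of 13 lymphocyte genes 5 rose (10 over the list alone; median 1.75, adjusted p = 1.93e-08), with JCHAIN, a component of secreted antibodies, at 511 ± 209 against 20.7 ± 10.3. Of 13 macrophage genes 7 rose, and 7 over the list alone (median 2.02, adjusted p = 0.000132), with LYZ, lysozyme, at 341 ± 295 against 13.4 ± 5.27. With an estimated correlation the adjusted p was 0.365 for the first 4 of these lists and 0.44 for macrophages.

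Some matrix genes fell. The mean log2 value of the elastic fibre list was 8.30, 7.71 and 7.28 in Fused replicates 1 to 3. The means of the erythroid list there were 7.06, 9.21 and 9.35, with haemoglobin reads of 1.55%, 5.64% and 6.41%. In Control the elastic fibre mean lay between 8.80 and 9.30, beside erythroid means between 3.41 and 4.67. In ISC replicates 1 to 3 the elastic fibre means were 9.15, 9.01 and 9.08, beside erythroid means of 5.98, 9.69 and 5.43. ISC replicate 2, with 5.00% haemoglobin reads, thus had an elastic fibre mean within the Control range. Of 16 elastic fibre genes 9 fell, and when adjusted over the list alone 13 fell and 1 rose (median -1.09, adjusted p = 5.34e-07). ELN (scaffold Un0067, 654638 to 665917) fell from 1480 ± 528 to 274 ± 133 (log2 change -2.49, adjusted p = 0.0169) and LOX, which cross-links elastin and collagen, from 4293 ± 659 to 462 ± 399 (log2 change -3.66, adjusted p = 0.0188). Of 15 fibrillar collagen genes 8 fell, and 10 over the list alone (median -1.01, adjusted p = 9.68e-07), and of 13 other collagens 7, and 8 over the list alone (median -1.39, adjusted p = 6.14e-06). COL3A1 fell from 14780 ± 5970 to 2878 ± 1750 (adjusted p = 0.0375), while COL1A1 was at 7239 ± 9420 in Fused and 4014 ± 1200 in Control (adjusted p = 0.997). Of 10 small proteoglycans 2 fell, FMOD and PRELP, and 5 over the list alone (median -0.91, adjusted p = 0.000892). Of 12 activated fibroblast genes 4 fell, among them FN1 and POSTN, while over the list alone 5 fell and 1 rose (median -0.54, adjusted p = 0.0348). With an estimated correlation the adjusted p was 0.365 for the elastic fibre, collagen and small proteoglycan lists and 0.434 for the activated fibroblast list. Of 8 synovial lining genes 3 fell, and 5 over the list alone (median -1.27, adjusted p = 0.00575; adjusted p = 0.365 with an estimated correlation), among them PRG4, lubricin, which went from 2830 ± 1060 to 100 ± 94.6, and HTRA4, from 274 ± 158 to 6.41 ± 6.55. Other large falls were those of CCL21, METTL11B, ANGPTL5, MMRN1 and THBS4, between -3.52 and -5.00 on the log2 scale.

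Smaller groups moved as well. Of 10 tested bone genes 2 rose, DMP1 and RUNX2, the transcription factor of osteoblasts, and 5 over the list alone (median 2.24, adjusted p = 0.00157; adjusted p = 0.426 with an estimated correlation). Of 18 interferon-induced genes 3 rose, CMPK2, RSAD2 and IFIT3, and 4 over the list alone (median 0.53, adjusted p = 0.00686; adjusted p = 0.443 with an estimated correlation). Of 12 inflammatory genes 3 rose, CXCL8, CXCL12 and IL1B, and 4 over the list alone (median 0.64, adjusted p = 0.0329; adjusted p = 0.396 with an estimated correlation and 0.0545 with the replicate block). Of 14 genes of endoplasmic reticulum stress 2 fell, DDIT3 and HSPA5, and over the list alone 2 fell and 1 rose (median -0.41, mean -0.08, adjusted p = 0.0389; adjusted p = 0.365 with an estimated correlation and 0.0794 with the replicate block). Lists of protease inhibitors, TGF-beta signalling, mural cells, tendon and ligament, glycolysis and hypoxia, skeletal muscle and immediate early genes shifted down and ribosomal proteins up (median 0.24), with adjusted p between 0.000138 and 0.037, and between 0.365 and 0.76 with an estimated correlation. Over all genes 2, 1, 2, 2, 2, 0, 0 and 0 of their members were called in this order, and 4, 2, 2, 3, 3, 0, 0 and 0 over the list alone. The cartilage list did not shift (adjusted p = 0.772): its median was 0.59 and its mean 0.35, while the test ranked it lower. TGFB1, CTGF, ACTA2, FBN1, ACAN, SOX9 and COL2A1 did not pass (adjusted p between 0.0508 and 0.567), and MMP2 fell from 1140 ± 459 to 425 ± 176 (adjusted p = 0.05 as rounded). The skeletal muscle median was -2.82, and -1.21 without Control replicate 1, which had the highest mean log2 value of this list (7.34, against 1.13 and 4.27 in Control replicates 2 and 3), and -4.32 without Control replicate 2. Without single libraries, with the calls kept, the median was 1.11 for bone (Fused replicate 2), 0.37 for inflammatory (Fused replicate 3), 0.32 for interferon (Control replicate 1), 0.39 and 0.41 for ribosomal protein (Control replicate 1 and Fused replicate 2) and -0.83 for activated fibroblast genes (Fused replicate 1). By fry, 5 lists passed: lymphocyte, erythroid, granulocyte and mast cell, synovial lining and endoplasmic reticulum stress.

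The count of 966 genes rested on single libraries. With limma it was 0 without Control replicate 1, Control replicate 2, Fused replicate 2 or Fused replicate 3. Between 2348 and 2811 genes then had an unadjusted p under 0.05, and edgeR also gave 0 in each case. The limma count was 342 without Control replicate 3 (2 with edgeR) and 2191 without Fused replicate 1 (2187 with edgeR). All 966 genes kept their direction each time, which was fixed beforehand since the groups of each called gene did not overlap. The count was 25 in a fit of all 9 libraries, 50 without the trend, 1878 with array weights, 815 with edgeR (734 shared) and 1371 with DESeq2 (909 shared). Without Fused replicates 2 and 3, richest in haemoglobin reads, limma called 0 genes (1924 at an unadjusted p under 0.05), with the spread of the lone Fused library taken from Control, and the count of 23 lists became 12. List calls were lost without Fused replicate 1 for interferon (adjusted p = 0.111, median 0.34), inflammatory (0.0765), endoplasmic reticulum stress (0.105), immediate early (0.0765) and ribosomal protein genes (0.111), and without Fused replicate 2 for inflammatory (0.0522), TGF-beta (0.0592) and tendon and ligament genes (0.0734). They were lost without Fused replicate 3 for activated fibroblast (0.156, median -0.13), mural (0.11), tendon and ligament (0.11), immediate early (0.0578), endoplasmic reticulum stress (0.0561) and ribosomal protein genes (0.5, median 0.10). They were lost without Control replicate 1 for immediate early (0.65, median 0.02) and tendon and ligament genes (0.0681), without Control replicate 2 for inflammatory (0.0556), endoplasmic reticulum stress (0.0798) and ribosomal protein genes (0.349, median 0.13), and without Control replicate 3 for endoplasmic reticulum stress (0.0807) and ribosomal protein genes (0.101).

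**Figure D2:**
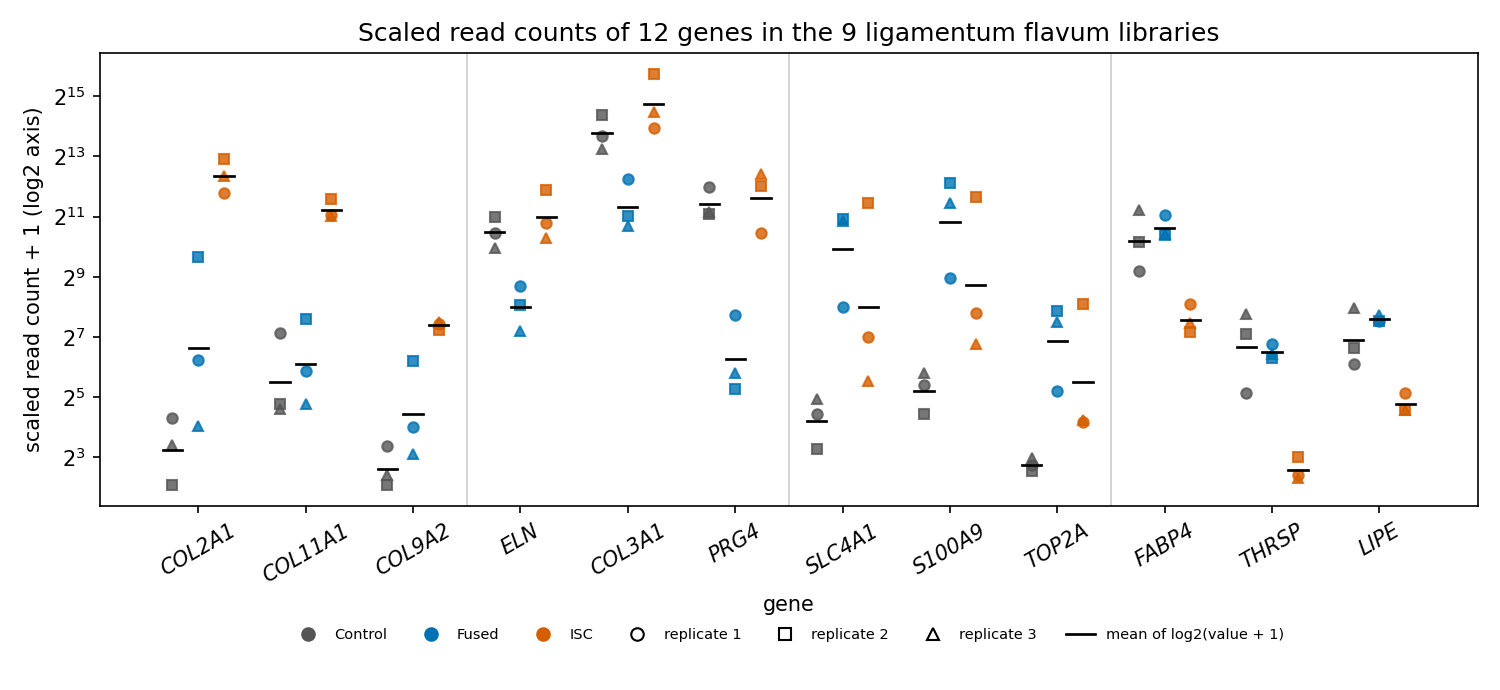
Scaled read counts plus 1 of 12 genes on a log2 axis, with groups as colours, replicates as shapes and a bar at the mean of log2(value + 1); grey lines part cartilage, matrix and lubricin, blood and cell cycle, and adipocyte genes. COL2A1 lies between 3555 and 7738 in ISC and between 3.19 and 18.9 in Control, and FABP4 is lower in each ISC library than in each other library.

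ISC was compared with Fused to ask how the stressed level differed from the fused level. Some cartilage genes were higher in ISC and some adipocyte genes lower, and matrix lists shifted up with at most 2 members of each collagen, elastic fibre and small proteoglycan list called. With an estimated correlation no list kept its call (adjusted p of 0.158 or more). CILP, a cartilage matrix protein (chromosome 17, 7080560 to 7095372), was at 1323 ± 352 (SD, n = 3) in ISC and 27.2 ± 10.8 in Fused, a log2 change of 5.59 (SE 0.316, adjusted p = 0.00275). CHAD, chondroadherin, was at 1573 ± 295 against 90.3 ± 41.4 (adjusted p = 0.012), PRG4 at 3664 ± 2090 against 100 ± 94.6 (adjusted p = 0.0369) and COL11A1 at 2403 ± 545 against 92.8 ± 89.2 (adjusted p = 0.0312). ANGPTL5, CYTL1, PCOLCE2 and SRPX2 were higher by 4.72, 4.70, 3.81 and 3.77 on the log2 scale, and SOX9 by 2.38 (adjusted p = 0.0369). PRG4, CILP, ANGPTL5, PCOLCE2 and SOX9 were lower in each Fused library than in each Control library, so their differences include a fall in Fused. PRG4 was at 2830 ± 1060 in Control and changed by 0.218 in ISC against Control (limma adjusted p = 0.899). For CHAD, COL11A1, CYTL1 and SRPX2 the Fused and Control libraries overlapped. In all, 31 genes were higher and 12 lower among 15404 tested; groups did not overlap in 15.4% of the tested genes, where chance gives 10%.

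Of 11 adipocyte genes 6 were lower over all genes and 11 when adjusted over the list alone (median -2.83, adjusted p = 1.30e-18; adjusted p = 0.158 with an estimated correlation). FABP4, a fatty acid carrier (chromosome 3, 97155361 to 97159722), was at 197 ± 66.6 in ISC and 1609 ± 451 in Fused (log2 change -3.04, adjusted p = 0.0278). LIPE, hormone-sensitive lipase, was at 26.7 ± 6.61 and 192.5 ± 17.9 and THRSP at 5.15 ± 1.74 and 89.85 ± 15.2 (adjusted p = 0.012 and 0.0124). KLB, CIDEA, CIDEC, MC5R and ASPA were lower by between -3.25 and -4.05 on the log2 scale. In Fused against Control the adipocyte list did not shift (median 0.13, adjusted p = 0.695).

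Of 17 cartilage genes 4 were higher over all genes and 12 over the list alone (median 2.96, adjusted p = 2.42e-14; adjusted p = 0.158 with an estimated correlation). Among matrix lists, 2 of 16 fibrillar collagen genes were higher, PCOLCE2 and PLOD2 (median 1.39, adjusted p = 1.54e-12), 1 of 13 other collagens, COL16A1 (2.15, 3.31e-11), 0 of 16 elastic fibre genes (1.28, 1.47e-09) and 0 of 10 small proteoglycans (1.99, 3.54e-09). Over the list alone 12, 9, 10 and 8 of their members were higher, and the fibrillar collagen median was 2.08 without Fused replicate 2. With an estimated correlation their adjusted p was 0.245, and 0.158 for small proteoglycans. ELN was at 2257 ± 1320 against 274 ± 133 and ACAN at 2568 ± 1110 against 132 ± 85.4 (adjusted p = 0.0678 and 0.0509). Protease inhibitors (1 of 7 higher, SERPINE2, and 6 over the list alone), TGF-beta signalling, activated fibroblast, tendon and ligament, glycolysis and hypoxia, endoplasmic reticulum stress, synovial lining (1 of 7 higher, PRG4, and 2 over the list alone; median 0.32, mean 1.73) and skeletal muscle lists were also shifted up. Interferon, lymphocyte, granulocyte and mast cell, cell cycle, erythroid, endothelial, bone, ribosomal protein and respiratory chain lists were shifted down, the blood lists beside haemoglobin reads of 5.00% in ISC replicate 2 and at most 0.480% in ISC replicates 1 and 3. Adjusted p of these lists lay between 3.07e-08 and 0.0362, and between 0.245 and 0.702 with an estimated correlation. By fry, 4 lists passed: adipocyte, cartilage, small proteoglycan and protease inhibitor. The synovial lining median was 0.75 without ISC replicate 1 and 0.51 without ISC replicate 2, with the call kept. Without ISC replicate 3 it was 0.097, with the call lost.

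The count of 43 genes was 0 with limma without Fused replicate 3 (1059 at an unadjusted p under 0.05; edgeR 0), and 3, 24, 9, 12 and 15 without Fused replicate 2, Fused replicate 1, ISC replicate 1, ISC replicate 2 and ISC replicate 3. In this order edgeR gave 0, 0, 0, 14 and 8 (987, 1156, 1193, 1937 and 951 at an unadjusted p under 0.05). It was 0 without the trend (1557 at an unadjusted p under 0.05; 34 with edgeR), 74 with median centring, 79 with no filter, 82 with array weights, 88 with the replicate block, 214 in a fit of all 9 libraries and 321 with DESeq2. Without ISC replicate 2 and Fused replicates 2 and 3, richest in haemoglobin reads, limma called 0 genes (878 at an unadjusted p under 0.05), with the spread of the lone Fused library taken from the 2 remaining ISC libraries. List calls of cell cycle and erythroid genes were lost without Fused replicate 2 (adjusted p = 0.209 and 0.157), Fused replicate 3 (0.0767 and 0.15), ISC replicate 1 (0.175 and 0.225) or ISC replicate 3 (0.414 and 0.312). Those of granulocyte and mast cell genes were lost without Fused replicate 2 (0.0921) or ISC replicate 3 (0.159), and those of synovial lining genes without Fused replicate 2 (0.0749), Fused replicate 3 (0.0517) or ISC replicate 3 (0.232). Bone genes lost theirs without Fused replicate 2 (0.235), ISC replicate 1 (0.142) or ISC replicate 2 (0.0767), endothelial genes without Fused replicate 1 (0.0997), and respiratory chain genes without Fused replicate 2 (0.256) or ISC replicate 1 (0.153). Ribosomal protein genes lost theirs without Fused replicate 3 (0.0655) or ISC replicate 2 (0.0672), and skeletal muscle genes without Fused replicate 1 (0.15), Fused replicate 3 (0.109) or ISC replicate 1 (0.685, median -0.38).

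**Figure D3:**
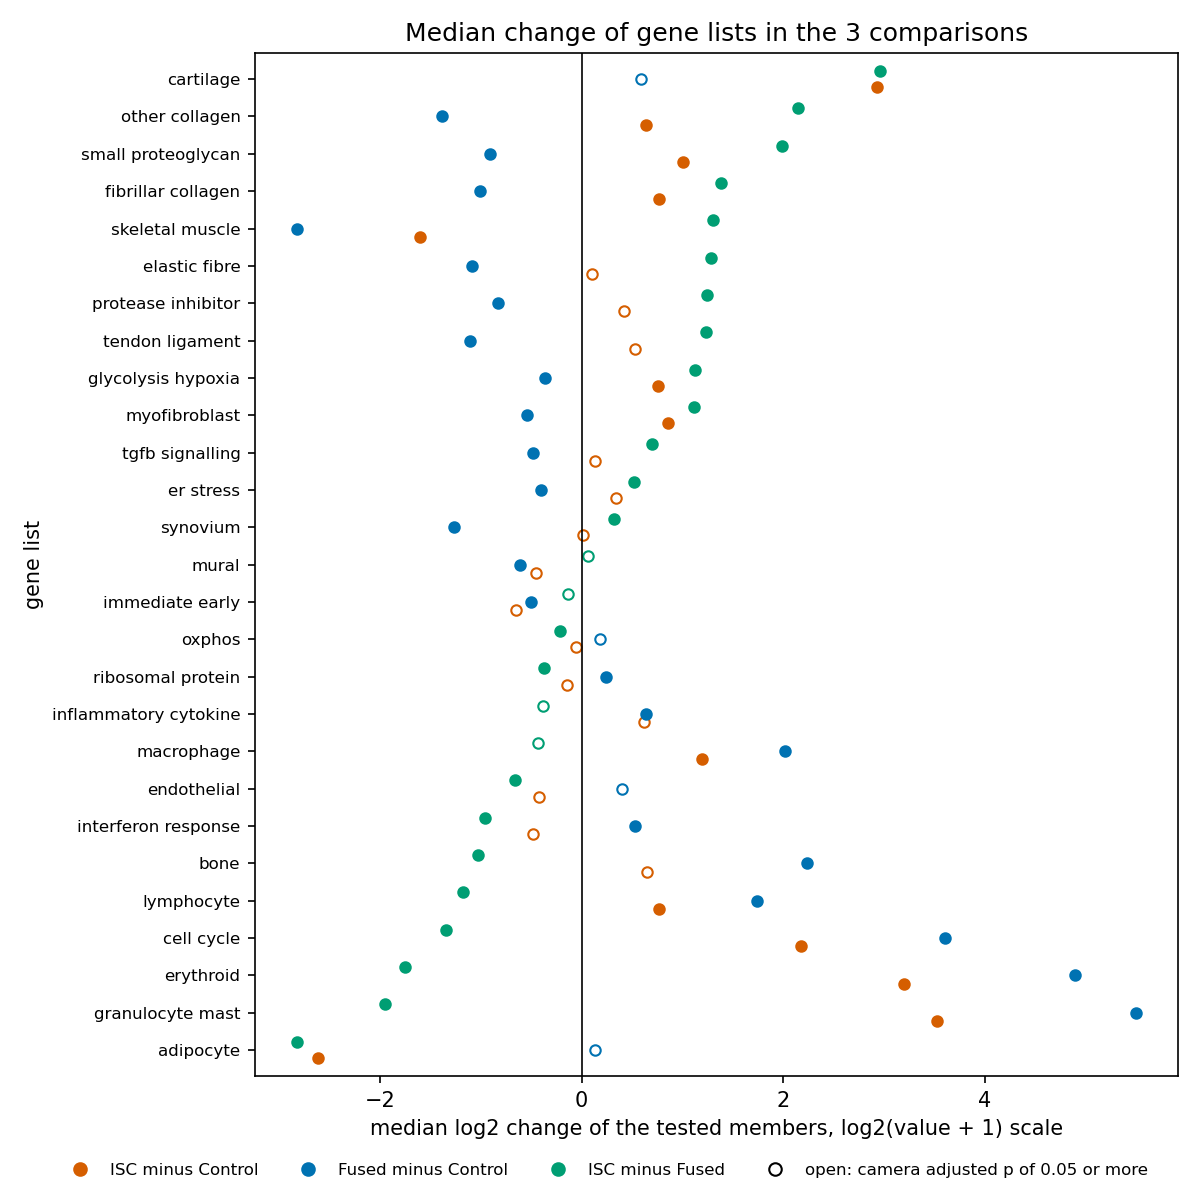
Median log2 change of the tested members of each gene list past the test in at least 1 comparison; colours are the 3 comparisons and open points did not pass (myofibroblast stands for activated fibroblast, synovium for synovial lining and oxphos for respiratory chain genes). The cartilage list lies at 2.93 and 2.96 in the comparisons of ISC, and the adipocyte list at -2.62 and -2.83.

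The changes at both operated levels against the same Control libraries were also set side by side. Across 14033 genes tested in both, which are not independent replicates, the log2 changes of ISC and of Fused against Control correlated with r = 0.634 and a covariance of 0.45. Unchanged groups simulated against shared controls gave r = 0.501 and a covariance of 0.12 (mean of 100 simulations), a difference in covariance of 0.33. Without ISC replicate 2, rich in haemoglobin reads, r was 0.432, under the simulated r for all 9 libraries. Changes that the levels do not share lower r, and the simulation holds none, so this r does not decide whether changes were shared. The covariance was not computed without this library. Only RAB9A and LOC100358370 were called in the same direction in both. Neither was called in both without Control replicate 1, Control replicate 2, Fused replicate 2 or Fused replicate 3, where Fused against Control gave 0 genes. Independent lists would share 0.227 rising and 0.0272 falling genes, and the simulation, which holds no changed gene, gives no level for this overlap. With separate Control libraries, a test chosen after the results were seen, 1 library served a level and the others the other level. The 6 ways gave r between 0.334 and 0.581 and a covariance between 0.294 and 0.423 (mean 0.3615). The simulated r and covariance were made with shared controls and give no level for these ways. Each way kept the libraries richest in haemoglobin reads.

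In the authors' deposited tables, at their q-value threshold of 0.1, 1407 genes were called between Control and Fused (998 higher in Fused and 409 lower), 605 between Control and ISC (453 higher in ISC and 152 lower) and 527 between Fused and ISC (366 higher in ISC and 161 lower).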

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

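The tests of this part were planned, and 5 gene lists were singled out because they shifted up in ISC against Control and down in Fused against Control, so that the effects of the levels differed. The test of that difference is the list test of ISC against Fused, whose adjusted p was 1.544e-12 for fibrillar collagens, 3.314e-11 for other collagens, 3.541e-09 for small proteoglycans, 3.065e-08 for glycolysis and hypoxia genes and 5.829e-06 for activated fibroblast genes. With an estimated correlation the adjusted p was 0.2453, 0.2453, 0.158, 0.4096 and 0.2453 in this order. Because ISC minus Fused is the difference of the changes that singled these lists out, the direction of this test was fixed by that choice and its p is not independent evidence. The median log2 changes against Control were 0.77 in ISC and -1.01 in Fused for fibrillar collagens, 0.64 and -1.39 for other collagens, 1.001 and -0.91 for small proteoglycans, 0.75 and -0.37 for glycolysis and hypoxia genes, and 0.86 and -0.54 for activated fibroblast genes. Without ISC replicate 2 the ISC medians were 0.44 for fibrillar collagens, 0.34 for other collagens and 0.36 for glycolysis and hypoxia genes, with the calls of the last 2 lists lost. The activated fibroblast median was 0.54 in ISC without ISC replicate 3 and -0.13 in Fused without Fused replicate 3, with the call lost in each case. Both sets of changes share the Control libraries.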

How the results depend on the processing

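The settings with edgeR or DESeq2, without the libraries richest in haemoglobin reads, with the erythroid covariate and with separate controls were chosen after seeing the data. None of 85 gene calls taken by the rule for named genes reversed in the 19 to 23 settings run for each. These settings leave out the erythroid covariate for comparisons with Control. Without single libraries no reversal was possible, because the groups of each called gene did not overlap. Of these 85 calls, 0 were kept in each of their settings. The causes of the changes below were not tested, except that fewer libraries give less power. Genes changed between ISC and Control numbered 7, and 4 with a pseudocount of 0.1, 14 with all 9 libraries in a fit, 3 with the replicate block, 12 at a threshold of 0.1, 228 with DESeq2, 2 with edgeR without Fused replicate 2 and ISC replicate 3, 1 with the erythroid covariate, and 4 to 38 without single libraries. Their list calls numbered 13, and 0 with an estimated correlation, 1 with fry, 5 with the covariate and 10 to 21 without single libraries. Genes changed between Fused and Control numbered 966, and 50 without the trend, 1878 with array weights, 25 with all 9 libraries, 1792 at a threshold of 0.1, and 0 to 2191 without single libraries. They numbered 0 with edgeR without Fused replicate 2 (2180 at an unadjusted p under 0.05), 0 with limma without the haemoglobin-rich libraries (1924) and 0 with limma and the covariate (563). The covariate does not overlap between Control and either operated group, so these fits extrapolate and single genes and lists were not read from them; 654 of the 966 genes kept their direction in it. Their list calls numbered 23, and 0 with an estimated correlation, 5 with fry, 12 without the haemoglobin-rich libraries, 3 with the covariate and 17 to 23 without single libraries. Genes changed between ISC and Fused numbered 43, and 74 with median centring, 79 with no filter, 82 with array weights, 214 with all 9 libraries, 88 with the replicate block, 182 at a threshold of 0.1, 321 with DESeq2, 125 with the covariate and 0 to 24 without single libraries. They numbered 0 with limma without the trend (1557 at an unadjusted p under 0.05), 0 with edgeR without Fused replicate 2 and ISC replicate 3 (779) and 0 with limma without the haemoglobin-rich libraries (878). Their list calls numbered 23, and 0 with an estimated correlation, 4 with fry and 17 to 24 without single libraries. The correlation of 0.6338 was 0.5107 by rank, 0.473, 0.4905 and 0.3414 with Control replicates 1, 2 and 3 in turn kept for ISC and the others for Fused, 0.3339 and 0.4524 with Control replicates 1 and 2 kept for Fused and the others for ISC, and 0.4324 to 0.6737 without single libraries, and the overlap of 2 genes was 5 at a threshold of 0.1.

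Genes and lists read outside the covariate fits of comparisons with Control changed direction as follows. In ISC against Control, CTGF (0.1361) was at -0.06901 with quantile normalization, -0.2241 with edgeR without ISC replicate 3 and -0.5539 to 1.018 without single libraries, and MMP2 (-0.02705) at 0.08704 with edgeR, 0.08595 with DESeq2, 0.08275 without the haemoglobin-rich library and -0.5107 to 0.3468 without single libraries. In Fused against Control, COL1A1 (-0.008651) was at 0.02239 with quantile normalization, 0.8733 with edgeR and -1.12 to 0.6106 without single libraries, and ACTA2 (-0.7929) at -1.604 to 0.02316 without single libraries. Without the haemoglobin-rich libraries ACTA2 was at 0.8291, TGFB1 at -0.1274, LMOD1 at 0.08931 and the median of the mural list at 0.3307; the median of the immediate early list was -0.6915 to 0.01509 without single libraries. In ISC against Fused, ACTA2 (-0.08685) was at 0.03384 with median centring, 0.4184 with array weights and -0.9029 to 0.7241 without single libraries, and the median of the skeletal muscle list at -0.3779 to 2.0. With edgeR without Fused replicate 2 and ISC replicate 3, S100A9 was at 0.09667, EPB42 at 0.1889, CDK1 at 0.7477, BUB1 at 1.059 and AURKB at 0.4034, and with the covariate AURKB was at 0.03305 and the median of the cell cycle list at 0.2602. The replicate number was not taken as a pairing because the labels do not say which libraries share an animal. Residuals of libraries with the same number correlated with r of 0.186, -0.0697 and 0.0404 for ISC and Control. For Fused and Control r was -0.0456, -0.083 and 0.0463, and for ISC and Fused 0.391, 0.403 and -0.152. Pairs of ISC and Fused libraries with other numbers had r between -0.618 and 0.358. These values do not settle whether libraries of the same number share an animal. Genes with fewer than 3 reads in a library (scaled values of 2.40 to 3.58) are limited by depth.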

Other observations

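The tests on the level to which the marrow signal extends, on the cartilage list without ISC replicate 2, and on genes read on a single side were chosen after the results were seen. Lists that passed in no comparison included mechanoresponse genes, with medians of -0.13 in ISC and -0.06 in Fused against Control (adjusted p = 0.575 and 0.171), matrix proteases (0.11 and -0.27; 0.943 and 0.504), BMP signalling (-0.17 and -0.14; 0.478 and 0.504) and Wnt signalling (-0.14 and -0.20; 0.22 and 0.296). The mean differed in sign from the median and the test for the mechanoresponse list in ISC (0.10) and for matrix proteases in Fused (0.37). For matrix proteases in ISC the mean (0.19) and median were positive while the test ranked the list lower. Nerve genes had medians of -0.64 and 0.77 (adjusted p = 0.0618 and 0.928) and osteoclast genes 0.06 and 0.53 (0.732 and 0.752), with a mean of -0.06 and a lower rank in ISC. Single members were called over all genes in Fused against Control. There 1 matrix protease rose and 1 fell, 1 BMP gene rose, and 1 Wnt gene rose and 2 fell. In the same comparison 1 mechanoresponse and 2 nerve genes fell and 0 osteoclast genes were called. In ISC against Control 0 members of these lists were called.

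In Fused against Control 7 of 7 erythroid and 7 of 9 granulocyte and mast cell genes rose over all genes, with the calls of these lists lost with an estimated correlation (adjusted p = 0.365). Mature blood without precursors is argued against by 13 genes of marrow precursors. Their median log2 change was 4.216 in Fused against Control, with 13 of 13 higher. The median of the granulocyte and mast cell list stayed at 5.444 after quantile normalization (8 of 9 higher). This does not test the authors' scaling, because a size factor shifts the genes of a library nearly alike. The median log2 change over all 14686 tested genes was already 0.0245, so a list this far above it had to stay high. A change confined to the fused level is argued against by the same precursors in ISC (median 2.976, 12 of 12 higher): the highest ISC library lay 5.526 above the highest Control library on the log2 scale, and ISC replicates 1 and 3 lay 1.654 and 0.7756 above it, where the Control libraries spanned 0.6218. Marrow or blood-rich tissue taken with the ligament, or formed at the operated levels, remains a candidate explanation that these libraries leave open.

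Of 17 cartilage genes 4 rose in ISC against Control over all genes and 13 did not pass, among them ACAN and SOX9. The list shifted up (median 2.93, adjusted p = 1.56e-14), a call lost with an estimated correlation (adjusted p = 0.333). ISC replicate 2, rich in haemoglobin reads, is argued against as the sole source by the mean log2 values of the list. They were 7.13, 6.92 and 7.25 in ISC replicates 1 to 3 and between 3.66 and 4.51 in Control. The median without ISC replicate 2, 2.734 (15 of 17 higher), follows from these values and is no separate evidence. Surface cartilage of a facet joint cannot be told apart from a change in the ligament: PRG4, abundant at that surface, changed by 0.218 (95% interval -1.02 to 1.45) and its upper bound lay just under 1.464, the bound set beforehand, but its Control level of 2830 is far above the 62.49 that the called cartilage genes reach there, so a small share would be hidden. Disc nucleus tissue cannot be told apart either: the median of 6 genes was -0.05707, under the bound of 0 set beforehand by less than the spread of the members (SE 0.418), of which 3 were higher. A change of the ligament itself at the stressed level is a hypothesis that was not tested here and stays open beside tissue taken with the samples.

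Some genes were read in each library of 1 side and in none of the other when Control was set against the 6 operated libraries. There were 53 such genes (36 without reads in Control and 17 without reads in the operated libraries). Of 84 splits of the 9 libraries only the real one gave as many, and the highest of the other splits gave 48. That other split sets Fused replicates 2 and 3 and ISC replicate 2, with the most haemoglobin reads, apart, and a minimum of 1 read lies under the 3 reads below which counting error limits values. With at least 2, 3, 5 and 10 reads there were 10, 4, 3 and 1 genes against 5, 5, 2 and 0 in the highest other split. At 3 reads 2 of 84 splits, the real one included, gave as many, and the real split was not the highest. At 5 reads these were RAB9A, at least 22.4-fold higher in the operated libraries (floor of 3 reads per library), MCEMP1 (scaffold Un0069, 799644 to 802285), at least 17.7-fold higher, and LOC100344154 (chromosome 10, 12911713 to 12912190), at least 2.75-fold lower. Each fold rests on the mean of the side that was read. MCEMP1 was at 130.8, 54.66 and 71.61 in Fused replicates 2 and 3 and ISC replicate 2, richest in haemoglobin reads. In Fused replicate 1 and ISC replicates 1 and 3 it was at 9.29, 6.434 and 5.016. Differences between animals cannot be told apart from the operation for the 53 genes, since no animal is known to be in both groups. The mean of the erythroid list did not overlap between Control and either operated group. Blood cell content therefore cannot be told apart from the operation either.

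For each pair of groups the 6 libraries make 10 splits, too few for a share under 0.05. The numbers of splits that gave as many include the real split. ISC against Control gave 7 genes where the highest other split gave 1 (1 split gave as many), and 13 lists where it gave 17 (5 splits gave as many). Fused against Control gave 966 genes against 0 (1 split gave as many) and 23 lists against 20 (1 split). ISC against Fused gave 43 genes against 749 (2 splits gave as many) and 23 lists against 19 (1 split). The split with 749 genes sets Fused replicate 1 and ISC replicates 1 and 3 against Fused replicates 2 and 3 and ISC replicate 2, which hold the most haemoglobin reads, and points to a structure of the samples. Other splits called 3 to 20 lists, so the list test with a preset correlation called lists in each of these splits within a pair of groups.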
